A study of Gallus gallus with 6 samples.

How the data were processed

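Total RNA was extracted from the cultured cells of each sample, and biotin-labelled cRNA made from 5 µg of it was hybridised to an Affymetrix chicken array, per the labels' protocols. The deposited values are on a log2 scale and were made with GCRMA, which corrects background from probe sequence, normalizes between arrays and summarises each probe set, per the submitters' processing notes. Its version, the chip definition and whether all 6 arrays were processed in 1 run are not given in the sources used here. The 6 columns do not share 1 distribution (medians 2.98 to 3.26, upper quartiles 5.81 to 6.38), and they were used as deposited. Values run from 1.23 to 16.20 with a dense floor near 2 to 3, and between 14770 and 15398 probe sets per array read above 4. No detection flags were used.

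The 96 array control probe sets were left out. In the platform annotation 27168 of the other 38439 probe sets carry 1 gene symbol, 177 several and 11094 none; symbols were looked up through gene identifiers in the RefSeq table of the chicken assembly GRCg7b, which changed 0 of them, and no coordinates were used. A probe set was tested if it read above 4 on at least 3 of the 6 arrays, whichever group they were in. A gene is represented by its tested probe set with the highest mean over all 6 arrays, and no gene was named from a probe set with several symbols. Of the tested genes 3322 had more than 1 tested probe set.

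EGR4 and empty vector samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with 1 shared spread per probe set and Benjamini-Hochberg adjustment over all tested probe sets. Differences are EGR4 minus empty vector on the log2 scale. Where every array of 1 group read under 4, the fold is a lower bound, the bright group's mean against the higher of 4 and the dim group's mean, and values under 4 were given no order. Where only some arrays of a group read above 4, the fitted difference is given and depends on values near the floor. Named genes follow a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among called genes with non-overlapping groups, the EGR and NAB genes, 11 fibroblast genes whatever their result, and up to 4 called members of each list. Members that pass only with the block, and others named as examples, were chosen after their values were seen.

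The 23 gene lists, fixed before the data were examined, cover matrix, contractile, TGF-beta, cell cycle, signalling, stress, metabolic and cell type marker genes. Lists with at least 5 tested genes were tested with limma's camera (correlation preset to 0.01, and estimated), with Benjamini-Hochberg adjustment over the lists. Without the block, the calls of the collagens, other matrix proteins, contractile genes and the epithelial, adipocyte and endothelial markers held with the estimated correlation. Those of the other 6 called lists did not, and with the block none held. With an estimated correlation, camera uses only the few degrees of freedom that 6 arrays leave, and fewer with the block. A lost call there therefore does not show that a list's members vary together. The estimated correlation of the collagens, 0.0057, lay under the preset 0.01, yet their camera adjusted p rose from 2.5e-09 to 0.0297.

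The groups share replicate numbers in the sample titles. Equally numbered samples deviated together from their group means, with correlations across probe sets of 0.798, 0.811 and 0.888 for replicates 1, 2 and 3. Replicates 1 and 2 share the contrast with replicate 3, and across the groups their unequally numbered samples had correlations of 0.559 and 0.607. The first principal component separates replicate 3. The numbers were therefore taken to pair the samples, and a fit with the replicate number as a block, planned as an alternative, is given beside the results whose calls it changes. It called 486 genes instead of 42. The labels do not say what the numbers share.

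The fits were tested on simulated data with the real probe set levels, the real shifts between replicate pairs and 200 changed probe sets in each of 5 simulations of this comparison over 15159 probe sets. Without the block 0%, 0%, 9.6% and 66.4% of changes of 1, 2, 4 and 8 (log2) were recovered, and with it 7.6%, 88.8%, 99.6% and 100%, with no wrong direction. False calls made up 0% of the calls without the block and 8.19% with it. Of 20 unshifted simulated lists, camera called 0. The simulated genes varied independently, so this does not show how camera with the preset correlation treats lists whose members vary together. In the data the estimated correlation was 0.438 for the cell cycle list and 0.544 for the cholesterol synthesis list, among the highest of all lists. It was 0.0057 for the collagens, 0.013 for the other matrix proteins and 0.050 for the contractile genes. For the epithelial, adipocyte and endothelial markers it was 0.191, -0.0018 and -0.047.

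Alternatives planned before the data were examined were no filter, a filter at 6, quantile normalization, median centring, values under 4 raised to 4, an intensity trend with robust variance, an unmoderated statistic, the block, the mean of a gene's probe sets, stricter thresholds, an estimated correlation, and each array left out. After the data were examined, fits without both replicate 3 arrays, the block without each pair, and the block with quantile normalization were added. Figures were drawn with matplotlib 3.10.9.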

Results

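Transcript levels were measured in cultured skin fibroblasts from 10-day chicken embryos that had been infected with a retrovirus. In 3 samples the virus carried no insert (empty vector), and in the other 3 it carried EGR4, a zinc-finger transcription factor of the early growth response family. The study's title places EGR4 in the setting of fibrosis, the excess build-up of collagen-rich matrix, and the comparison asks which genes differ when EGR4 is supplied. Each sample was read on 1 Affymetrix chicken array, where 15159 of 38439 probe sets were bright enough to be tested, and 12640 of these stand for 7730 named genes. The design text calls the samples biological replicates and says nothing more about how the cultures arose. The number of arrays, 3 per group, limits the precision of every value.

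EGR4 itself separated the groups. Its sense probe set read 12.91 ± 1.04 (log2, SD, n = 3) in the EGR4 cells and 2.72 ± 0.60 (SD, n = 3) in the empty vector cells, which is at least 482-fold higher (log2 difference 10.20, SE 0.68, adjusted p = 0.0139). The 3 EGR4 arrays read 12.60, 12.07 and 14.07, and the 3 empty vector arrays read 2.44, 2.30 and 3.40. A second EGR4 probe set, whose name marks it as antisense (a strand that could not be checked here), read 11.13 on EGR4 replicate 3 and no more than 2.57 on the other 5 arrays. With 1 array left out, the adjusted p of EGR4 was 0.0289 without EGR4 replicate 3 but 0.138 and 0.0871 without EGR4 replicates 1 and 2, and 0.161, 0.0883 and 0.0543 without empty vector replicates 1, 2 and 3.

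Both replicate 3 arrays stood apart from the other 4. Over the tested probe sets their Pearson correlation with the other arrays, across probe sets, was 0.507 to 0.621, against 0.846 with each other and 0.860 to 0.952 among the other 4. The first principal component held 71.4% of the variance and separated replicate 3, and the second held 18.6% and separated EGR4 from empty vector. The bacterial and phage hybridisation controls averaged 13.18 and 13.16 (log2) on the replicate 3 arrays and 9.50 to 10.23 on the others. The beta-actin signal at the 3' end exceeded that at the 5' end by 0.91 to 1.54 on the other 4 arrays, and the difference was 0.02 and -0.03 on the replicate 3 arrays.

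**Figure D1:**
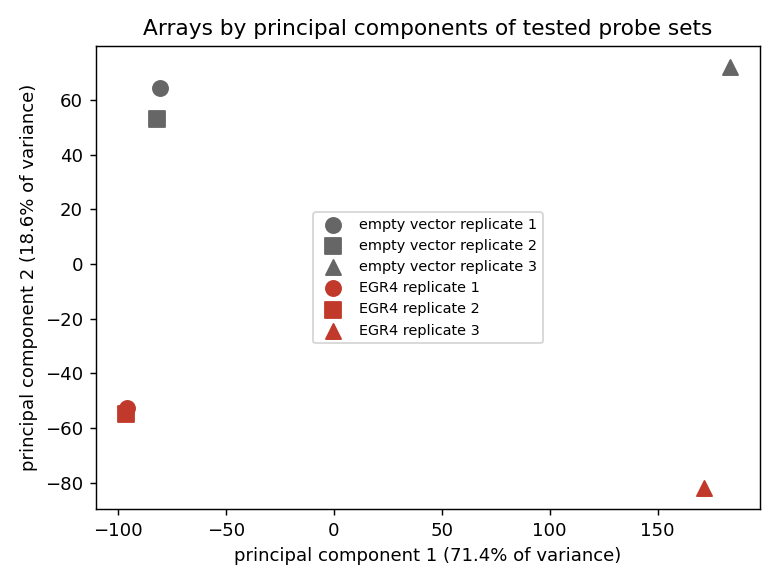
Each point is 1 array, placed by its scores on the first and second principal components of the 15159 tested probe sets, with colour for the group and shape for the replicate number. The horizontal axis (71.4% of the variance) sets both replicate 3 arrays apart, and the vertical axis (18.6%) sets the 3 EGR4 arrays below the 3 empty vector arrays.

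Besides EGR4, the genes called without the block included rises of FABP5, MUC4L and CP and falls of LUM, CXCL14 and CCN3. FABP5, a fatty acid binding protein, was at least 481-fold higher (adjusted p = 0.00656), MUC4L, a mucin gene, at least 337-fold higher (adjusted p = 0.00656) and CP, the copper-carrying ferroxidase ceruloplasmin, at least 228-fold higher (adjusted p = 0.0257). LUM, the collagen-binding proteoglycan lumican, fell by 8.53 on the log2 scale (SE 0.81, adjusted p = 0.0257), and CXCL14, a chemokine, fell by 8.25 (SE 1.03, adjusted p = 0.0454), each with 2 of 3 EGR4 arrays above 4. CCN3, a matricellular protein, was at least 83.6-fold lower (adjusted p = 0.0316). In all, 42 of 7730 genes changed, 22 upward and 20 downward, at an adjusted p under 0.05 in limma. With the replicate number as a block 486 genes changed, 221 upward and 265 downward.

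All 42 genes were also called with the block, where the fitted difference is the same by design. All 486 had the same sign in the 3 pairs of equally numbered arrays, which a call with the block nearly requires. The fitted differences of the 42 genes ran from 3.44 to 10.38 in size on the log2 scale, and 22 of them had every array of 1 group under a value of 4, where only a bound on the fold can be given. Of the 42 genes, 17 had a second tested probe set, which differed in the same direction in all 17. Across the array, 816 genes (10.6%) had groups that did not overlap, where chance gives 10% if all 6 arrays vary alike, which the shift of replicate 3 prevents. Of all genes, 4204 (54.4%) had the same sign in all 3 pairs, where chance gives 25% for a single gene. All genes share the same 3 pairs and do not vary independently, so their share can lie far from 25% by chance. With both replicate 3 arrays left out, 81 genes changed, 36 upward and 45 downward, and 530 changed with the block. The count of 42 fell to 17 without EGR4 replicate 3 and to 0 without any other single array. At an unadjusted limma threshold of 0.05 there were then 347, 376 and 486 genes without empty vector replicates 1, 2 and 3 and 357 and 361 without EGR4 replicates 1 and 2. The blocked count was 146 without the replicate 1 pair and 137 without the replicate 2 pair. With any pair left out, a blocked fit has little spread of its own per probe set and leans on the variance that limma pools over probe sets. Its false calls were not simulated, so these counts, the 530 included, are weak checks.

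Among the genes called without the block, 12 rises and 12 falls were chosen by fitted difference, with no order given to values under 4, and genes called only with the block can differ by more. The other 8 rises were those of FABP4, FRMD4B, CA2, CD36, KRT14, EPB41L3, LINGO3 and ADH1C. FABP4, the fat-cell fatty acid binding protein, rose by 7.34 on the log2 scale (SE 0.95), and CD36, a fatty acid translocase, was at least 41.7-fold higher. CA2, a carbonic anhydrase, was at least 41.9-fold higher, and ADH1C, an alcohol dehydrogenase, at least 20.3-fold higher. KRT14, a keratin of basal epidermis, rose by 6.38 (SE 0.82) and FRMD4B by 6.51 (SE 0.67; 5.60 with values under 4 taken as 4, with 1 of 3 empty vector arrays above it). EPB41L3, a membrane skeleton protein, and LINGO3 were at least 38.4-fold and 30.7-fold higher. The adjusted p of these 8 genes lay between 0.0139 and 0.0488.

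The other 9 falls were those of COMP, WISP2, ENPP3, FAM180A, LSAMP, IRAG1, FBLN5, FHL1 and TNFRSF11B. COMP, the cartilage oligomeric matrix protein, fell by 6.67 on the log2 scale (SE 0.72), WISP2, a CCN family protein, by 5.81 (SE 0.66) and ENPP3, a nucleotide pyrophosphatase, by 7.09 (SE 0.69). FAM180A fell by 7.55 (SE 0.63). For it and ENPP3 only 1 of 3 EGR4 arrays read above 4, so that with values under 4 taken as 4 the differences were -6.70 and -6.55. LSAMP, a cell adhesion protein, fell by 5.96 (SE 0.47) and IRAG1 by 4.72 (SE 0.61). FBLN5, an elastic fibre protein, was at least 18.3-fold lower, FHL1, a LIM domain protein, at least 35.3-fold lower, and TNFRSF11B, the decoy receptor osteoprotegerin, at least 28.7-fold lower. The adjusted p of these 9 genes lay between 0.0164 and 0.0489.

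**Figure D2:**
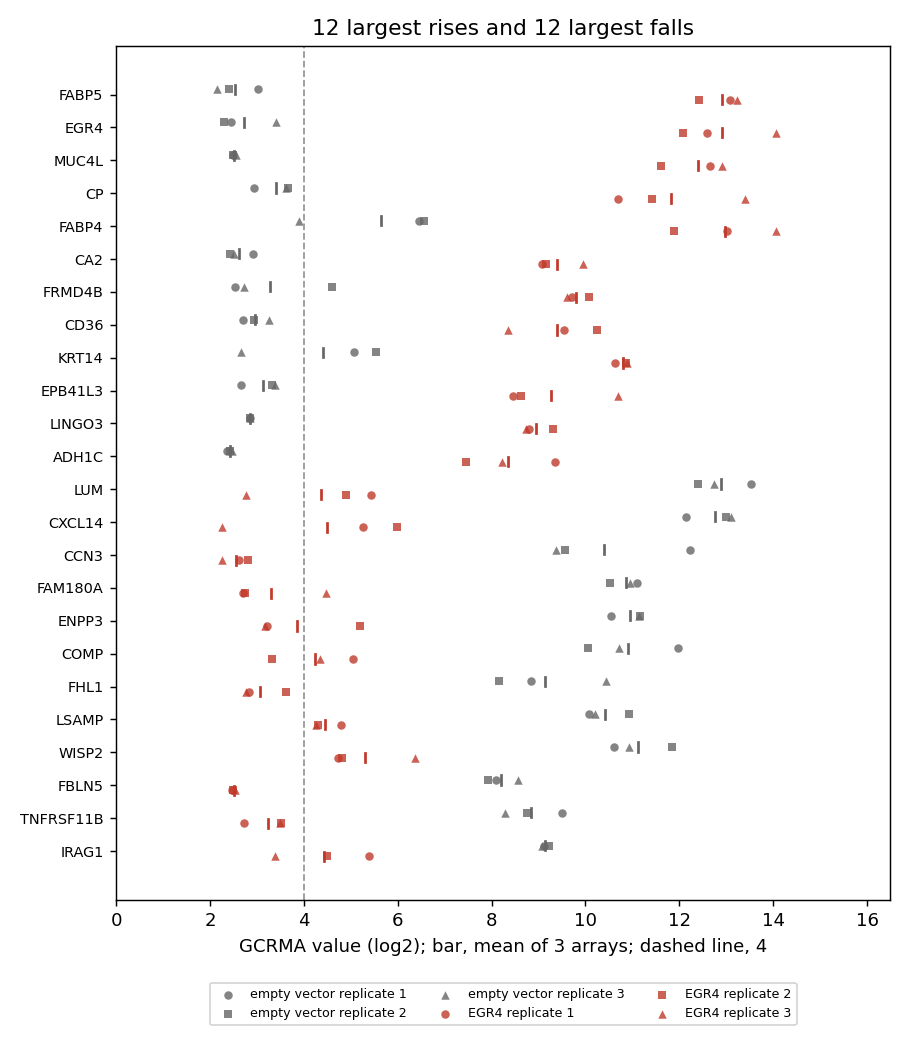
Log2 GCRMA value of each array for the 12 genes with the largest fitted rise and the 12 with the largest fitted fall among those called without the block, empty vector in grey and EGR4 in red, with a bar at each mean of 3 arrays and a dashed line at 4, the lowest value used for testing. The 3 EGR4 arrays lie on 1 side of the 3 empty vector arrays in all 24 genes, and FABP5 reads 12.91 on average with EGR4 and 2.53 with empty vector.

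Of the matrix lists, 22 of 28 tested matrix proteins other than collagens and 14 of 16 tested collagens had lower values with EGR4. Of the 28, 3 fell and 25 did not pass (median log2 difference -1.68; 8 fell adjusted over the list alone): LUM and FBLN5, above, and ELN, elastin, which fell by 4.65 on the log2 scale (SE 0.50, adjusted p = 0.0316; 1 of 3 EGR4 arrays above 4). With the block 9 fell, among them THBS2, a thrombospondin, by 5.55 (adjusted p = 0.00575), MFAP5, a microfibril protein, by 3.59 (adjusted p = 0.0164) and TGFBI by 2.24 (adjusted p = 0.0143). Of the 16 collagens 0 passed in the fit without the block (median -0.88; 4 fell adjusted over the list alone), and with the block 6 fell, including COL8A1 by 7.36 (adjusted p = 0.0150; -6.16 with values under 4 taken as 4, with 1 of 3 EGR4 arrays above it), COL6A3 by 2.74 (adjusted p = 0.0377) and COL8A2, which was at least 12.3-fold lower (adjusted p = 0.0154). The main fibrillar chains COL1A1, COL1A2 and COL3A1 had log2 differences of -0.45 (SE 0.41), -0.77 (SE 0.57) and -0.41 (SE 0.55). Neither they nor FN1, fibronectin (-0.36, SE 0.42), nor POSTN, periostin (-0.26, SE 0.53), passed with or without the block. These are the brightest probe sets of each gene, and the dimmer tested ones of COL1A2 and COL3A1 differed more, from -0.79 to -1.51 in COL1A2 (lowest blocked adjusted p 0.0508) and from -0.55 to -0.99 in COL3A1. With 1 array left out the printed differences ran from -0.51 to -0.39 in COL1A1, -1.18 to -0.47 in COL1A2 and -0.71 to -0.10 in COL3A1. They ran from -0.45 to -0.22 in FN1 and -0.53 to 0.03 in POSTN. The SE of COL1A1 is moderated over probe sets, while its arrays had SDs of 0.12 with empty vector and 0.03 with EGR4. Its pairwise differences were -0.55, -0.44 and -0.36. The 8 tested FN1 probe sets ran from -0.19 to -2.07, and only the lowest passed, with the block (adjusted p = 0.0256). Its name marks it as antisense, a strand that could not be checked here. So do the names of the FN1 probe sets at -0.19 and -0.30 and of the COL3A1 probe set at -0.55. The probe sets that represent COL1A1 and FN1 were above 14 on every array, near the top of the range. A difference there may be poorly measured, which was not tested.

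Against all other genes, camera gave a downward shift with an adjusted p of 4.98e-11 for the other matrix proteins and 2.5e-09 for the collagens, and adjusted p = 0.0297 with an estimated correlation for both, or adjusted p = 0.182 with an estimated correlation and the block. Without the filter the median of the other matrix proteins was -0.58 over 41 genes and that of the collagens -0.77 over 23, both past the camera threshold. The 20 tested genes of collagen processing and crosslinking shifted down (median -0.96, and -1.17 without EGR4 replicate 1 to -0.60 without EGR4 replicate 3; adjusted p = 2.61e-05), with adjusted p = 0.156 with an estimated correlation. None of them passed alone, adjusted over the list alone included, and with the block CTSK, cathepsin K, fell by 4.06 (adjusted p = 0.0186) and P4HA3, a prolyl hydroxylase subunit, by 2.38 (adjusted p = 0.0193). The 16 tested matrix proteases and inhibitors had a median of -0.41 (adjusted p = 0.0291, and adjusted p = 0.156 with an estimated correlation). It ran from -0.81 without empty vector replicate 2 to -0.24 without empty vector replicate 1. Of these genes 0 passed, 0 adjusted over the list alone, and 4 fell with the block: FAP, the fibroblast activation protein, by 2.60 (adjusted p = 0.0332), RECK by 1.87, TIMP2 by 1.56 and ADAM33 by 1.61. The camera call of the proteases was lost without empty vector replicate 3 (adjusted p = 0.345), EGR4 replicate 1 (0.145) or EGR4 replicate 2 (0.150), and without the filter (adjusted p = 0.224, median -0.07 over 33 genes). Without the replicate 1 or the replicate 2 pair, the blocked fit called 5 and 5 of the other matrix proteins and 3 and 2 of the collagens, all downward, and without the replicate 3 pair 13 and 4. Of the processing genes it called 0 without the replicate 1 pair and CTSK alone without the replicate 2 pair. Of the proteases it called only TIMP4, upward, without the replicate 1 pair and 0 without the replicate 2 pair.

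Of 32 tested contractile and myofibroblast genes 30 had lower values with EGR4. Of these 32 genes 0 passed without the block (median -0.92; 5 fell adjusted over the list alone), and with it 7 fell: TAGLN, transgelin, by 3.28 (adjusted p = 0.0131, against 0.166 without the block), ITGA8, an integrin chain, by 5.70 (adjusted p = 0.0136; -4.86 with values under 4 taken as 4, with 1 of 3 EGR4 arrays above it), ACTG2, a smooth muscle actin, by 3.05 (adjusted p = 0.0158), TPM1 by 1.65, PDLIM5 by 1.59, PDLIM7 by 1.21 and MYOCD, the smooth muscle coactivator myocardin, by at least 2.75-fold. ACTA2, the smooth muscle actin that marks myofibroblasts, averaged 5.53 with empty vector, was under 4 on every EGR4 array and did not pass either fit (adjusted p = 0.507, and 0.0750 with the block). It passed without both replicate 3 arrays, both with the block (adjusted p = 0.0253) and without it. MYLK, a myosin light chain kinase, went the other way, with a log2 difference of 4.69 (SE 1.34, adjusted p = 0.453, and 0.0552 with the block), and was called only with the block and without both replicate 3 arrays. Camera gave an adjusted p of 2.79e-10 for the list, and adjusted p = 0.0398 with an estimated correlation, or adjusted p = 0.182 with an estimated correlation and the block. Without the replicate 1 or the replicate 2 pair the blocked fit called 3 (ACTG2, ITGA8 and TAGLN) and 2 (ACTG2 and ITGA8) of the list.

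In the TGF-beta list 20 of 29 tested genes had lower values with EGR4. Of these 29 genes 0 passed without the block (median -0.50; 2 higher and 1 lower adjusted over the list alone). With the block BAMBI, a pseudoreceptor that damps TGF-beta signalling, rose by 7.02 (adjusted p = 0.0186) and FST, the activin antagonist follistatin, by 3.35 (adjusted p = 0.0121), while 6 fell, including LRRC32, which holds latent TGF-beta at the cell surface, by 6.06 (adjusted p = 0.0127), SMURF2, a ubiquitin ligase that restrains TGF-beta signalling, by 2.32 (adjusted p = 0.0131), TGFB3 by 2.07 (adjusted p = 0.0476, against 0.464 without it) and SKI, a corepressor that also restrains it, by at least 3.82-fold (adjusted p = 0.0477). TGFB2 (log2 difference 0.57, SE 0.53), CCN2, the matricellular protein once named CTGF (-1.31, SE 0.54), and SERPINE2, a serine protease inhibitor (-1.64, SE 1.05), passed neither fit. With 1 array left out their differences ran from 0.33 to 0.93, -1.65 to -0.90 and -2.22 to -0.53. The list's camera call (adjusted p = 0.0108) did not hold with the estimated correlation, with adjusted p = 0.186 with an estimated correlation. It was also lost without empty vector replicate 3 (adjusted p = 0.345) or EGR4 replicate 1 (adjusted p = 0.0506). The blocked fit called BAMBI and FST higher and LRRC32 lower without the replicate 1 pair, and LRRC32 alone without the replicate 2 pair.

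**Figure D3:**
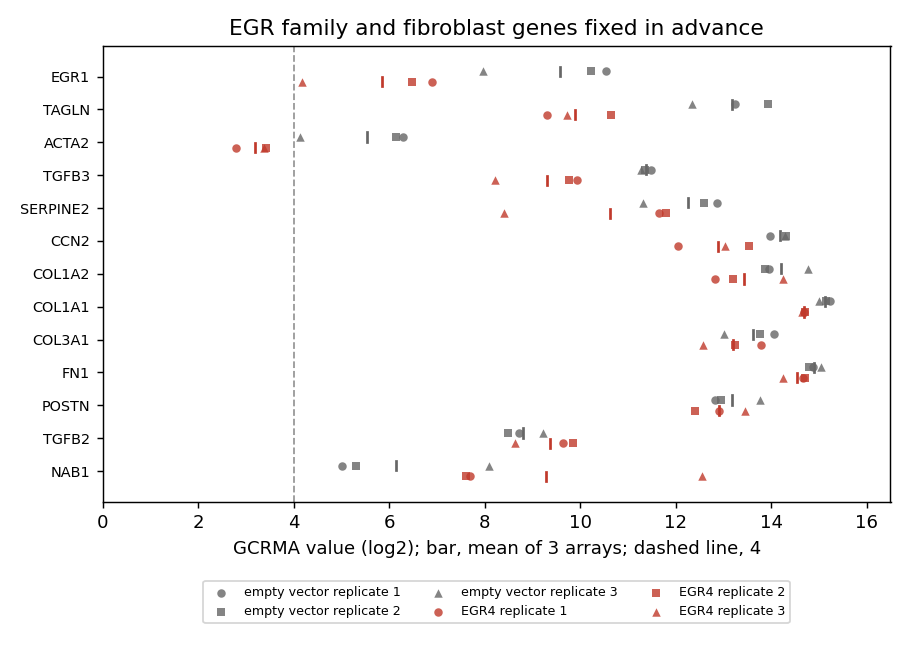
Log2 GCRMA value of each array for EGR1, NAB1 and 11 fibroblast genes fixed before the data were examined, empty vector in grey and EGR4 in red, with a bar at each mean of 3 arrays and a dashed line at 4. TAGLN averages 13.17 with empty vector and 9.89 with EGR4, while COL1A1 averages 15.13 and 14.68.

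Within the EGR family, EGR1 was lower in every pair where EGR4 was supplied. EGR1, an immediate early transcription factor, read 9.58 ± 1.40 (SD, n = 3) with empty vector and 5.85 ± 1.46 (SD, n = 3) with EGR4. Its pairwise log2 differences were -3.64, -3.76 and -3.79, so that it fell by 3.73 with the block (adjusted p = 0.00498) and did not pass without it (adjusted p = 0.414). NAB1, a corepressor of EGR proteins, rose by 3.15 with the block (adjusted p = 0.0328) and did not pass without it (adjusted p = 1.0). Its difference ran from 1.52 without EGR4 replicate 3 to 4.13 without empty vector replicate 3. EGR2, EGR3 and NAB2 have no named probe set on this array. Of the 16 tested genes of the EGR and immediate early list, 1 rose (EGR4 itself; 3 higher and 2 lower adjusted over the list alone). With the block 3 were higher, EGR4, NAB1 and ARC. No empty vector array read above 4 for ARC, and its difference was 1.32 with values under 4 taken as 4. In the same fit 3 were lower, EGR1, KLF2 by 2.36 (adjusted p = 0.0209) and the phosphatase gene DUSP1 by 1.55 (adjusted p = 0.0332). Without the replicate 1 or the replicate 2 pair the blocked fit called only EGR4 and EGR1. The list's camera test did not pass (median 0.64, and 0.0056 to 0.93 with 1 array left out; adjusted p = 0.315).

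Of 55 tested cell cycle and DNA replication genes 51 had a positive log2 difference (median 1.13). Camera gave the list an adjusted p of 5.19e-11, and adjusted p = 0.275 with an estimated correlation. Of these genes 0 passed without the block over all genes or adjusted over the list alone, and with the block 11 rose, or 38 adjusted over the list alone. TYMS, thymidylate synthase, rose by 2.35 with the block (adjusted p = 0.0167), RRM2, a ribonucleotide reductase subunit, by 2.32 (adjusted p = 0.0154), CDC20, an activator of the anaphase-promoting complex, by 1.91 (adjusted p = 0.0184) and MCM2, a replicative helicase subunit, by 1.71 (adjusted p = 0.0278). The median ran from 0.63 without empty vector replicate 3 to 1.74 without EGR4 replicate 3, and that of all tested genes from -0.29 to 0.48. Of the list, the blocked fit called 18 without the replicate 3 pair and 0 without the replicate 1 or the replicate 2 pair. The 19 tested cell cycle inhibitors and p53 targets had a median of -0.28 (-0.97 to 0.23 with 1 array left out; camera adjusted p = 0.254), with 0 passing in any count. CDKN1A had a log2 difference of -1.64 (SE 1.30). Their camera adjusted p was 0.0264 without EGR4 replicate 2, and 0.0136 with the block and without the replicate 2 pair.

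Among the markers of other cell types, 7 of 7 tested epithelial and 9 of 10 adipocyte genes had higher values with EGR4, and 6 of 6 endothelial genes had lower values. Of the epithelial genes 1 rose, KRT14 (5 adjusted over the list alone), and with the block 4 rose: KRT14, the tight junction gene CLDN1 by 4.51 (adjusted p = 0.00698; 3.65 with values under 4 taken as 4, with 1 of 3 empty vector arrays above it), KRT24 by 2.93 (adjusted p = 0.0327) and the junction gene JUP by 1.93 (adjusted p = 0.0296). Without the replicate 1 pair the blocked fit called 2 of them (CLDN1 and KRT14), and without the replicate 2 pair these and KRT7. The list's median was 4.38 (2.92 without empty vector replicate 1), with a camera adjusted p of 5.14e-10, and adjusted p = 0.0398 with an estimated correlation, or adjusted p = 0.182 with an estimated correlation and the block. The filter keeps genes that are bright in either group, and over all 19 epithelial genes on the array the median was 0.28, with 0 passing and a camera adjusted p of 5.00e-05. Of the adipocyte genes 2 rose, CD36 and FABP4 (3 adjusted over the list alone), and the block added FABP3 (at least 13.8-fold higher, adjusted p = 0.0316). FABP4 lost its call with values under 4 raised to 4, and both FABP4 and KRT14 lost theirs with the intensity trend and robust variance. PPARG, the nuclear receptor of fat-cell differentiation, had a log2 difference of 2.18 (SE 0.87) and passed neither fit. The adipocyte list had a median of 1.49 and a camera adjusted p of 7.03e-06, and adjusted p = 0.0398 with an estimated correlation, or adjusted p = 0.302 with an estimated correlation and the block. That median was 0.85 without EGR4 replicate 3, and without the filter it was 0.13 over 18 genes, with 0 passing and a camera adjusted p of 0.00159. Of the endothelial genes 0 passed (2 fell adjusted over the list alone), with a median of -1.47 and a camera adjusted p of 8.28e-05, and adjusted p = 0.0419 with an estimated correlation, or adjusted p = 0.218 with an estimated correlation and the block. Without the filter the endothelial median was -0.13 over 21 genes (camera adjusted p = 0.0174). With the block ERG fell by 2.10 (adjusted p = 0.0160), a call lost without the replicate 1 or the replicate 2 pair. Of the adipocyte genes the block kept CD36 and FABP3 without the replicate 1 pair and CD36 and FABP4 without the replicate 2 pair. Too few genes were tested for a group result in the skeletal muscle (3), melanocyte and Schwann cell (1), blood and macrophage (3) and cartilage and bone (3) lists. ACTA1, skeletal muscle actin, fell by 4.37 (SE 0.43, adjusted p = 0.0257), and with the block COL2A1 rose by 4.05 (adjusted p = 0.0350) and SPP1, osteopontin, by 3.25 (adjusted p = 0.0197), while no blood or melanocyte marker passed either fit.

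**Figure D4:**
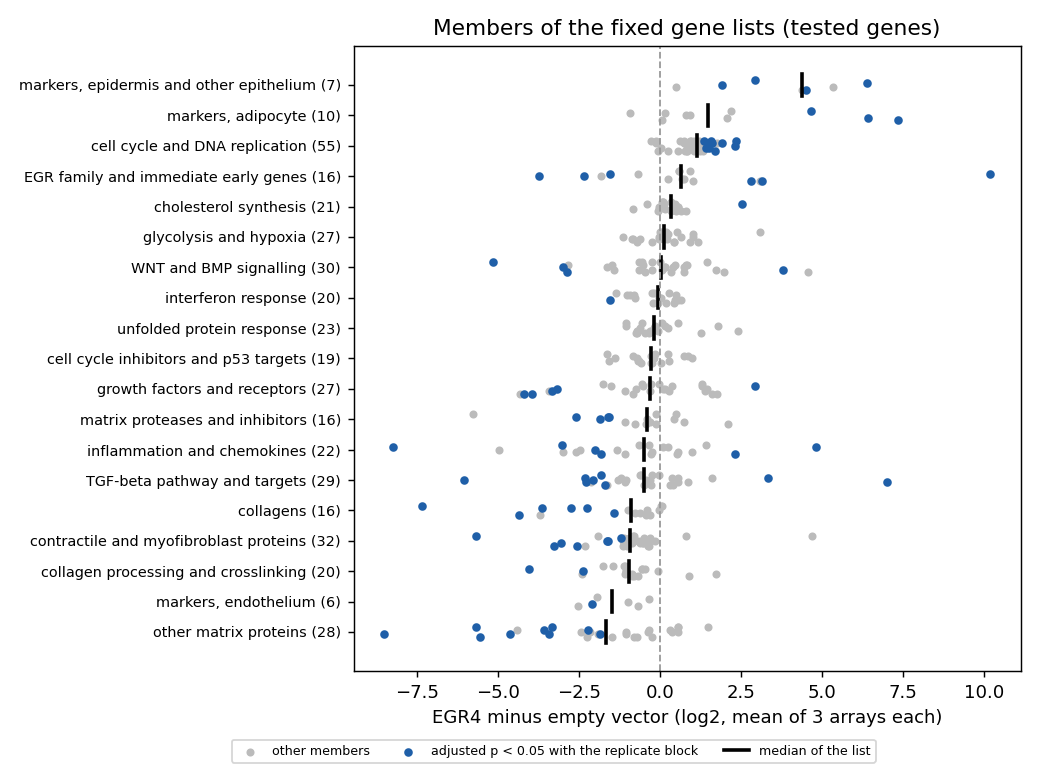
Log2 difference between EGR4 and empty vector for each tested gene of the 19 lists with at least 5 tested genes (number in brackets), with a black bar at each list's median and in blue the genes with an adjusted p under 0.05 when replicate number is a block. The medians run from -1.68 for the other matrix proteins to 4.38 for the epithelial markers.

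Signalling and inflammatory lists held members that moved in both directions. Of 22 tested inflammation and chemokine genes 1 fell, CXCL14 (2 higher and 3 lower adjusted over the list alone). With the block 2 rose, TLR7 and PTGS1, and 4 fell, CXCL14, IL18, CCL4 and NFKBIA. No empty vector array read above 4 for TLR7 or PTGS1. With values under 4 taken as 4 their differences were 4.10 and 0.60. That of IL18 was then -2.14, with 2 of 3 empty vector and 1 of 3 EGR4 arrays above 4. The list's median was -0.49 (camera adjusted p = 0.0108), with adjusted p = 0.187 with an estimated correlation, and it ran from -0.14 without empty vector replicate 1 to -1.11 without empty vector replicate 3. Of 27 growth factors and receptors 0 passed (1 higher and 4 lower adjusted over the list alone), and with the block FGFR3, a fibroblast growth factor receptor, was at least 3.53-fold higher (adjusted p = 0.0119). With the block BDNF, VEGFC, IGFBP7 and FGF7 fell, FGF7 by 3.97 (adjusted p = 0.0131). That list's median was -0.32 (camera adjusted p = 0.0194), with adjusted p = 0.324 with an estimated correlation. The inflammation call was lost without empty vector replicate 3 (adjusted p = 0.154) or EGR4 replicate 1 (adjusted p = 0.0855), and the growth factor call without empty vector replicate 3 (adjusted p = 0.245). Of 30 WNT and BMP genes 0 passed (1 lower adjusted over the list alone), and with the block BMP2 rose by 3.79 (adjusted p = 0.0277) and WNT9A, BMPER and FZD2 fell, WNT9A by 5.17 (adjusted p = 0.0204; 1 of 3 EGR4 arrays above 4). Without the replicate 1 pair the blocked fit called BMP2 and ID2 higher and WNT9A lower in that list, and without the replicate 2 pair 0. Of the inflammation list it called TLR7, CXCL12 and CXCL14 without the replicate 1 pair, and CXCL14 and IL1RL1 without the replicate 2 pair. Of the growth factors it called FGFR3, FGF7 and VEGFC without the replicate 1 pair, and these with IGFBP2 and IGFBP7 without the replicate 2 pair. The median of the WNT and BMP list was 0.03 (-0.30 to 0.16 with 1 array left out), with a mean of -0.12 and a camera direction downward (adjusted p = 0.510).

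No metabolic or stress list passed the camera test in the fit without the block. None of the 20 interferon response genes (median -0.05, camera adjusted p = 0.251), 21 cholesterol synthesis genes (0.33, adjusted p = 0.407), 23 unfolded protein response genes (-0.20, adjusted p = 0.309) or 27 glycolysis and hypoxia genes (0.12, adjusted p = 0.415) passed over all genes or adjusted over the list alone. With the block IFIH1, a sensor of viral RNA, fell by 1.54 (adjusted p = 0.0332) and HSD17B7, a sterol synthesis enzyme, rose by 2.54 (adjusted p = 0.0115). Both calls were lost without the replicate 2 pair, and that of IFIH1 also without the replicate 1 pair. With 1 array left out the medians ran from -0.20 to 1.05 for cholesterol synthesis, -0.19 to 0.03 for the interferon response, -0.34 to -0.12 for the unfolded protein response and 0.06 to 0.31 for glycolysis and hypoxia. For the unfolded protein response camera gave a downward shift with the block (adjusted p = 0.0489, and adjusted p = 0.560 with an estimated correlation) and, with the preset correlation, without both replicate 3 arrays (adjusted p = 0.0297). For cholesterol synthesis it gave an upward shift, with the preset correlation, without both replicate 3 arrays (adjusted p = 0.0231) or without EGR4 replicate 3 (adjusted p = 0.0439). With the block, no list in this series kept an adjusted p under 0.05 with an estimated correlation, the lowest being 0.182. That fit leaves few degrees of freedom, which limits what camera with an estimated correlation can call. The other matrix proteins ended at 0.182 although their estimated correlation with the block was -0.032. These results therefore cannot decide whether the shifts would hold.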

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

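The test of labelled strands at a value of 4 was planned before its result was seen, while the test at a value of 8 and the choice of which probe sets to list were made after the values were seen. Among 23280 probe sets too dim to be tested, 10 read above 10 on at least 1 EGR4 array and more than 6 (log2) above every empty vector array, a signal in probe sets outside the tested data; 1 probe set met the mirrored rule in the empty vector arrays. The antisense EGR4 probe set read 11.13 on EGR4 replicate 3, and probe sets without a gene name read 11.68 and 10.54 on the same array. CR1 (10.38), COBL (10.38), CPLX1 (10.30) and ANK3 (10.27 and 10.53 in 2 probe sets) were also brightest on EGR4 replicate 3. Of these, ANK3, COBL and CR1 also have tested probe sets, whose brightest ones had log2 differences of 4.63 for ANK3 (adjusted p = 0.0257), 3.22 for COBL (adjusted p = 0.673, and 0.0365 with the block) and 1.30 for CR1 (adjusted p = 1.0). FABP9 read 10.24 and 9.63 on EGR4 replicates 1 and 2 and 3.18 on replicate 3, and LYG2 read 10.72 on EGR4 replicate 2 alone. In all, 8 of the 10 were brightest on replicate 3.

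The antisense EGR4 signal on a single array was set against labelling of both strands on the replicate 3 arrays. Where the sense probe set of a sense and antisense pair read above 10, its antisense partner read above 4 in 81% of 21 pairs on EGR4 replicate 3, against 42.1% and 52.6% on EGR4 replicates 1 and 2 (1-sided Fisher's exact test, p = 0.0113). The same held for empty vector replicate 3, at 77.3% of 22 pairs against 36.8% and 45.5% (1-sided Fisher's exact test, p = 0.00639). At a value of 8, nearer to the signal of 11.13, the shares were 28.6% against 5.26% and 26.3% with EGR4 (p = 0.202, same exact test) and 27.3% against 10.5% and 18.2% with empty vector (p = 0.188, same exact test). These exact tests take probe set pairs as units and draw on the same pairs on each array. They set 1 array against 2, so their p-values measure no spread between arrays and cannot decide the question. Labelling of both strands on the replicate 3 arrays stays open as the source of a signal this bright. The strand was read from the probe set names alone, and antisense transcription from the provirus in that culture was not tested.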

How the results depend on the processing

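Fits without both replicate 3 arrays, the block without each pair, and the block with quantile normalization were chosen after the data were seen. The count of 42 changed genes (22 higher, 20 lower) moved to 13 (8 higher, 5 lower) without the filter, where 38439 probe sets share the adjustment, to 9 (6 and 3) with the unmoderated statistic, to 2 at an adjusted p under 0.01, and to 486 (221 and 265) with the replicate block. With values under 4 raised to 4 there were 28 (14 higher, 14 lower), all of them among the 42. Without both replicate 3 arrays 81 genes changed (36 and 45), and 530 (242 and 288) with the block. The block gave 146 (74 and 72) without the replicate 1 pair, 137 (56 and 81) without the replicate 2 pair and 458 (200 and 258) after quantile normalization. With each array left out in turn, the counts ran from 0 to 17 (0 to 10 higher, 0 to 7 lower), with fewer arrays behind each fit. All 42 genes kept their direction wherever they were tested (the filter at 6 tested 39 of them), and 10 of the 42 were called without the filter and 8 with the unmoderated statistic. The cause of the other changes was not tested.

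EGR4 kept a log2 difference of 8.91 to 10.62 over all settings, and lost its call with the unmoderated statistic (10.20, adjusted p = 0.0684) and without 5 of the 6 arrays (9.62 to 10.62 over the arrays left out). Its adjusted p ran from 0.00171 to 0.161 over the alternatives. The collagen, other matrix and contractile lists kept their downward shift under every alternative and their camera call in every fit with the preset correlation. The TGF-beta list (median -0.50) lost its call with an estimated correlation and without empty vector replicate 3 or EGR4 replicate 1, with medians of -0.74 to -0.44 over the arrays left out. The median of the growth factor list turned to 0.056 without EGR4 replicate 3, while camera still gave a downward shift (adjusted p = 0.00507). The median of all tested genes also moved there, from 0.11 to 0.48, so the turn is not particular to the list. Over the arrays left out the growth factor median ran from -0.53 to 0.056. Among the other 38 named genes and the 15 lists other than the collagen, other matrix, contractile and TGF-beta lists, the block ended no call made with the preset correlation, brought 4 genes and 1 list past the threshold and left 34 genes and 14 lists on their side.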

Other observations

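Several called genes outside the naming rule were chosen after their values were seen. NEBL, the actin-binding protein nebulette, rose by 5.35 on the log2 scale (adjusted p = 0.0257; 1 of 3 empty vector arrays above 4). ELOVL4, an elongase of very long chain fatty acids, was at least 15.5-fold higher (adjusted p = 0.0431), STK10, a serine/threonine kinase, at least 23.6-fold (adjusted p = 0.0257) and SEMA3A, a secreted guidance protein, at least 4.45-fold (adjusted p = 0.0454). SFTPA2 and MBL2, both collectin genes, were at least 6.71-fold (adjusted p = 0.0408) and 9.52-fold higher (adjusted p = 0.0488). HHIP, which binds hedgehog ligands, was at least 8.17-fold lower (adjusted p = 0.0461), and GEM, a small GTP-binding protein, fell by 3.44 on the log2 scale (adjusted p = 0.0486).

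The tests of hybridisation controls and of epidermal and fat-cell genes below were chosen after those values were seen, the rule for the fat-cell genes being changed once more after that, and the tests of probe sets of the same gene and of other splits before. The replicate 3 arrays of both groups stand apart. The 9 hybridisation control probe sets, whose targets do not come from the cells, averaged 3.32 (log2) higher on replicate 3 in the empty vector group and 3.41 in the EGR4 group. A different labelling or hybridisation run may account for this. The poly-A control probe sets showed no such shift, at 5.18 and 5.10 on the replicate 3 arrays and 4.55 to 6.79 on the other 4. They were dim, near the filter value of 4, and may be unable to show a shift, which was not tested. Over 3322 genes with at least 2 tested probe sets, the shift of replicate 3 against the others correlated between 2 probe sets of the same gene at only 0.221 (bootstrap interval 0.184 to 0.259), against 0.907 (0.892 to 0.918) for the difference between EGR4 and empty vector, which argues against transcript levels in the cultures as the whole cause. A difference between the cultures as part of the cause stays open. All 206 genes called with the block that have a second tested probe set showed the same direction in it.

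The joint rise of KRT14, CLDN1, FABP4 and CD36 was set against other cells in the EGR4 cultures. KRT5, CDH1, EPCAM, DSP, SFN, TP63 and CLDN4 are epidermal genes of the same list. They were under 4 in all 16 probe sets on every EGR4 array (7 of 7 genes, highest value 3.69), so the rise did not extend to them. They were picked, after the values were seen, from genes that had not risen, while all 7 tested genes of the list had higher values with EGR4. Their low values therefore cannot decide on epidermal cells as the source. JUP and the keratin gene KRT7 read 9.96 and 8.29 in the empty vector cells already. Of 5 fat-cell genes named on the array, ADIPOQ, PLIN1, CIDEA and GPD1 (4 genes) were under 4 on every EGR4 array, and CIDEC reached 4.18 with EGR4 but 4.61 with empty vector, so that 0 of the 5 fat-cell genes rose above both 4 and the empty vector arrays, while FABP4 averaged 12.98. These genes too were picked after the values were seen, while 9 of 10 tested adipocyte genes had higher values with EGR4. They therefore cannot decide on fat cells as the source. Nor is it known whether these epidermal and fat-cell probe sets can read their transcripts, since apart from CIDEC no array here shows them above 4. A response of the fibroblasts to EGR4, which the design names, may account for the rise and was not tested separately.

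The 6 arrays can be split into groups of 3 in 10 ways, and without the block the real split gave 42 genes and the highest of the others 0, so that 1 of 10 splits gave as many. Of the 4 splits that part all 3 pairs, with the block 1, the real one, gave as many genes (486), and the highest of the others gave 0; those exchange the groups within 1 pair. Neither number of splits can give a share under 0.05.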
